A study of Arabidopsis thaliana with 6 samples.

How the data were processed

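Total RNA from rosette leaves of soil-grown Arabidopsis thaliana was measured on 6 Affymetrix ATH1 arrays, 3 from the pad4 mutant and 3 from the pad4 est1b double mutant. Per the labels' protocols, RNA was isolated with a Qiagen RNeasy kit and labelled with biotin by the 3' IVT Express procedure, which copies RNA from its poly(A) end. The deposited values are probe set intensities (signals) on a linear scale, and MAS5 and GCOS are named in the submitters' processing notes; versions, settings and detection calls are not given in the sources used here. The values show that each array had been scaled to a 2%-trimmed mean of 100.0. Every column carried the name of 1 sample, so groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates came from separate plants or cultures, so p-values measure the spread between these samples alone.

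Genes were named only through the platform annotation given for the arrays. Of 22810 probe sets, 64 are Affymetrix controls, 13513 have 1 gene, 503 have several and 8730 have none listed; 13436 of the probe sets with 1 gene matched a gene of the TAIR10.1 reference table, which served for current names alone. The build behind the array annotation is not given, so no coordinates are printed. Most names are loci, since 11933 of the named probe sets carry only a locus identifier. Probe sets with several genes or with none are left unnamed.

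Signals were used as deposited, with an offset of 10% of the trimmed mean (10 signal units) added before log2. Control probe sets and probe sets with a mean signal under 20 over the 6 arrays were left out, which kept 12804 probe sets, 6892 of them (53.8%) with 1 gene. Fold changes are on the log2(signal + 10) scale, double mutant over pad4, which understates the change of dim genes. The double mutant was compared with pad4 in limma 3.58.1 (lmFit and eBayes, R 4.3.3), two-sided, without covariates, and p-values were adjusted by the Benjamini-Hochberg method over all probe sets kept, with a threshold of 0.05. The precision is limited by the number of arrays, 3 per group. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

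Gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, with 1 probe set per gene (the brightest) and at least 3 genes kept, adjusted over the lists of a family. Of the lists, 28 with 350 genes were set by name, and the genes encoded in the 2 organelles made 2 more. Only 55 of the 350 genes have a probe set that names them alone, so 9 of the 30 lists could be tested; 21 held fewer than 3 genes, 14 of these none that was kept. A second family of 19 lists, 18 of which kept enough genes to test, was built from the named probe sets once the annotation was known and before any fold change was computed. Each list was also tested with an estimated correlation and with fry.

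The settings of the main fit, the lists and the rule for the genes to be named were chosen before the data were examined. The rule takes the 2 mutated loci and the neighbours of EST1B. It takes the 12 largest changes per direction among called probe sets with 1 gene and with groups that do not overlap; where fewer pass, all that pass and then the smallest p-values up to 6 per direction, said not to pass. From each list set beforehand it takes up to 4 members by p-value if the list or a member was called, and otherwise up to 2. Exceptions are COR15A and the 5 further reported NMD targets, added to show all measured members, and the genes of the closing part, named after their values were seen.

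Alternatives changed 1 choice at a time: the offset, the filter on dim probe sets, quantile normalization or median centring, the replicate number as a block, the developmental stage of the labels as a covariate, only the samples labelled 5.10, probe sets open to cross-hybridisation left out, eBayes with trend and robust options, array weights, and each array left out in turn. The control 3'/5' ratio as a covariate and a fit without both replicate 3 arrays were added after the arrays had been seen. A planned test of transcript features that trigger nonsense-mediated decay, such as introns behind the stop codon, needs an annotation of untranslated regions and was not run.

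The procedure was tested on simulated data drawn from the means and spreads of the 12804 probe sets, 3 arrays against 3, in 5 runs with 200 changed probe sets each. It recovered 82.4% of the probe sets changed by 2 on the log2 scale and 7.2% of those changed by 1, with 22 false calls among 470. A simulated list of 9 probe sets, all raised by 1 on the log2 scale, was called in 5 of 5 runs, and 0 of 100 unchanged lists were called. Lists with smaller shifts, or with only some members raised, were not simulated. The simulated probe sets vary independently, so these counts check the procedure and do not give the error rate of list tests on arrays that share variation, where 8 of the 9 other splits called at least 1 fixed list.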

Results

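The series asks which transcripts differ when EST1B is lost in addition to PAD4. EST1B is a factor of nonsense-mediated mRNA decay (NMD), the pathway that removes transcripts with premature stop codons and some normal transcripts with upstream reading frames or long 3' ends. PAD4 is a lipase-like regulator of salicylic acid defence. The pad4 group carries the pad4-1 mutation and the double mutant carries pad4-1 together with an insertion in EST1B. Each group has 3 arrays. Total signal per array ran from 3405664 to 3894818 units and the median signal from 21.2 to 31.6. The labels give developmental stage 3.90 for pad4 replicates 2 and 3 and 5.10 for pad4 replicate 1 and the 3 double mutant samples, while the growth conditions described are the same for all 6.

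None of the loci that would check the genotypes could be read. EST1B, PAD4 and the neighbours of EST1B, AT5G19390 and AT5G19410, have no probe set that names them alone here, so the labels were taken as given.

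In the main fit 5 probe sets were called higher in the double mutant and 0 lower. That fit has no term for the replicate number. With the number as a block limma called 70 higher and 11 lower. Smaller decreases may have been missed, since 7.2% of simulated changes of 1 on the log2 scale were recovered. The largest rises were those of PDF1.2 and PDF1.2b, plant defensins of the jasmonate and ethylene branch of defence. PDF1.2 (AT5G44420) went from 311 ± 125 signal units in pad4 to 3907 ± 1377 in the double mutant (SD, n = 3), a log2 fold change of 3.62 ± 0.37 (SE), or 12.3-fold. PDF1.2b (AT2G26020) went from 331 ± 43.5 to 3893 ± 1270 (SD, n = 3), a log2 fold change of 3.47 ± 0.31 (SE). The coding sequences of the PDF1.2 genes are nearly identical and the PDF1.2b probe set is of a type that can cross-hybridise, so the change cannot be assigned to either gene.

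The other rises called in the main fit were those of AT3G53400, CPUORF47 and a probe set without a listed gene. AT3G53400, a gene with a conserved upstream open reading frame and a reported NMD target, went from 51.8 ± 18.5 to 398 ± 86.6 signal units (SD, n = 3), a log2 fold change of 2.75 ± 0.31 (SE). CPUORF47 (AT5G03190), named after its conserved peptide upstream open reading frame, went from 16.4 ± 0.60 to 110.7 ± 17.2 (SD, n = 3), a log2 fold change of 2.19 ± 0.24 (SE). Its 3 pad4 values (16.1, 17 and 15.9) lie under the filter of 20 units, so it was kept only through the double mutant. Its fold change thus depends on the offset (2.75 without it, 1.59 with 30%). The unnamed probe set went from 68.3 ± 7.72 to 423 ± 111 (SD, n = 3), with a log2 fold change of 2.44. In each of the 5 probe sets all 3 double mutant samples lay above all 3 pad4 samples.

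**Figure D1:**
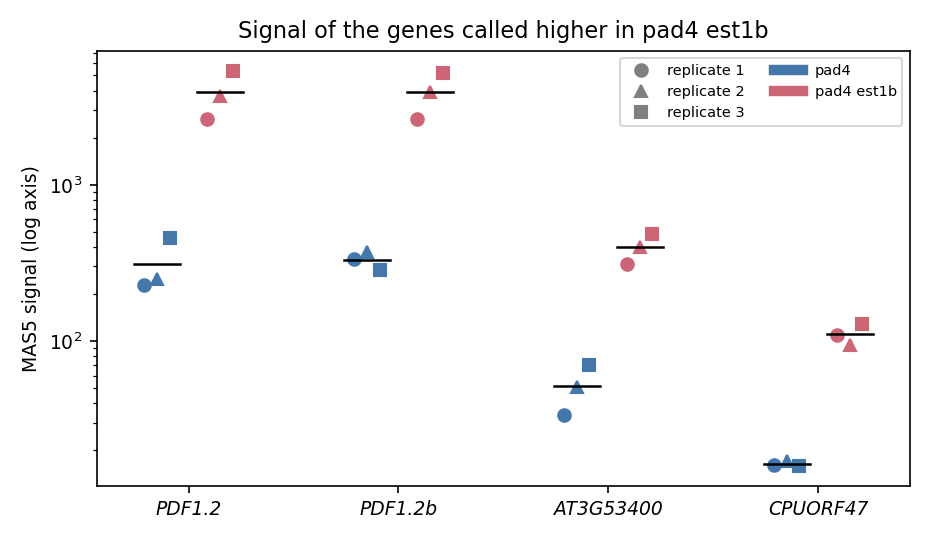
MAS5 signal (log axis) of the 4 named genes called higher in the double mutant, with 1 point per array, marker shape for the replicate number, colour for the genotype and a bar at the mean of each group. The double mutant points of PDF1.2 lie between 2652 and 5380 units and the pad4 points between 227 and 455.

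By limma the adjusted p was 0.036 for PDF1.2b and 0.0495 for PDF1.2, AT3G53400, CPUORF47 and the unnamed probe set. At an unadjusted p under 0.05 limma gave 569 probe sets, 421 higher and 148 lower, where 640 would be expected from uniform p-values. That number is no baseline for these arrays, which share variation: other splits of the 6 arrays into 3 and 3 gave from 6 to 4128. With the replicate number as a block limma gave 1604. A count under 640 therefore does not show that the genotypes are alike. The groups did not overlap in 1256 of 12804 probe sets (9.8%, against 10% by chance), 821 of them higher in the double mutant and 435 lower. The calls sit close to the threshold: limma called 0 probe sets without the offset, without the filter, with stage as a covariate, among samples labelled 5.10 or without probe sets open to cross-hybridisation, 2 with quantile normalization, 1 with median centring and, with array weights that had not converged, 2274 (1140 higher, 1134 lower). With the replicate number as a block limma called 81 probe sets, 70 higher and 11 lower, all 5 included. It called 0 without pad4 replicate 1 or 2 or without double mutant replicate 2 or 3, 1 without double mutant replicate 1 and 9 without pad4 replicate 3. In 2 fits chosen after the arrays had been seen it called 36 with the control 3'/5' ratio as a covariate and 19 without both replicate 3 arrays, all higher and all 5 included. The log2 fold changes themselves ran from 3.36 to 3.99 for PDF1.2, 3.14 to 3.73 for PDF1.2b, 2.39 to 3.21 for AT3G53400 and 1.59 to 2.75 for CPUORF47 over all alternatives.

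The next genes by p-value did not pass. On the higher side these were AT4G26555, from 152 ± 6.58 to 686 ± 114 signal units (SD, n = 3; log2 fold change 2.09, adjusted p = 0.052 by limma), and AT3G29375, from 31.6 ± 2.83 to 124 ± 11.1 (SD, n = 3; log2 fold change 1.69, adjusted p = 0.13 by limma). On the lower side AT2G05540 had a log2 fold change of -1.70 and AT3G53980 of -1.51. For AT5G48490, the log2 fold change was -1.16, and for AT4G30450 it was -1.05. AT1G77700 and AT1G68670 had -0.96 and -0.95. The adjusted p of these 6 genes lay between 0.58 and 0.76 by limma, and the smallest for any probe set with a lower signal in the double mutant was 0.45. With the replicate number as a block, limma called AT2G05540 (adjusted p = 0.0060), AT3G53980 (0.020) and AT5G48490 (0.034) lower, although the numbers were not taken as pairs.

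The list of reported NMD targets, set from general knowledge, was called higher in the double mutant at camera's preset correlation. It was not called by camera with an estimated correlation (adjusted p = 0.18). Of the 24 genes of the list only 9 could be read, since the others have no probe set that names them alone here. The median log2 fold change of these 9 was 0.76, and 8 of the 9 had a positive value. AT3G53400 passed over all genes. AT1G36730, which encodes translation initiation factor eIF5, had a log2 fold change of 2.35 ± 0.49 (SE) and went from 96.3 ± 62.7 to 496 ± 203 signal units (SD, n = 3). AT5G45430, a protein kinase gene, had 2.23 ± 0.44 (SE). For SACL1, a relative of the transcription factor SAC51 with a conserved upstream open reading frame, the value was 1.32 ± 0.40 (SE). Adjusted over all genes 1 of the 9 passed; adjusted over the list alone 4 passed, these same 4 genes, all higher. Of the rest, AT2G29210 had a log2 fold change of 0.76, UPF3 of 0.57, AT3G63340 of 0.53, SAMDC2 of 0.32 and SAMDC1 of -0.03.

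**Figure D2:**
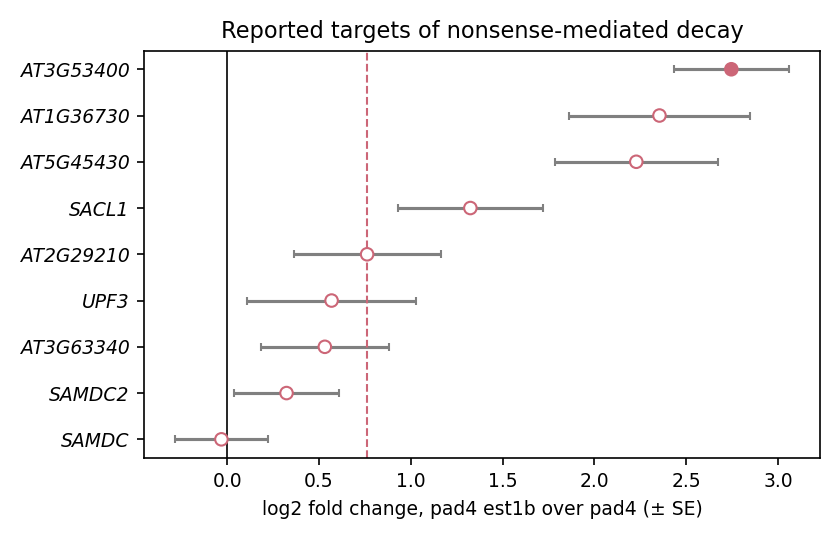
Log2 fold change (double mutant over pad4) of the 9 reported NMD targets, of 24 on the list, that could be read. Bars give the SE and a filled point marks the gene past the adjusted threshold. A solid line lies at 0 and a dashed line at the median. AT3G53400 lies at 2.75, the median at 0.76 and SAMDC1, drawn as SAMDC, at -0.03.

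The list had an adjusted p of 3.53e-09 by limma's camera at the preset correlation and adjusted p = 0.18 with an estimated correlation (the estimated value was 0.25), so the call is lost there. By fry the adjusted p was 0.097, and fry's p for change in either direction was 4.4e-05 before adjustment. The list was set from general knowledge of the field, and whether any member was first reported from these samples is not known here. The median was 0.36 among the samples labelled 5.10, which leave 1 pad4 array (replicate 1) against 3, assumed to vary like the others. The same list also differed between arrays of 1 genotype: its median was -0.83 in replicate 3 against replicate 1 of pad4 and -0.52 in the double mutant.

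The other lists of RNA decay and upstream reading frames were not called in the fit of all 6 arrays without covariates. Only 8 of the 20 listed genes with conserved upstream open reading frames and 5 of the 11 of the NMD machinery could be read. Among 8 genes with conserved upstream open reading frames, the median log2 fold change was 0.06, with AT3G53400 passing over all genes and 2 members, AT3G53400 and SACL1, adjusted over the list alone (camera adjusted p = 0.17; 0.38 as the adjusted p with an estimated correlation). In that list the methyltransferase gene PMEAMT (NMT2) had -0.70 and SAMDC2 0.32, neither passing. The NMD machinery (5 genes) had a median of 0.18 (-0.17 with stage as a covariate) and a camera adjusted p of 0.28, and was called only without pad4 replicate 1 (adjusted p = 0.042; adjusted p = 0.91 with an estimated correlation over all arrays); BTZ, a component of the exon junction complex, had 1.26 ± 0.39 (SE) and UPF3, which is also on the target list, 0.57 ± 0.46 (SE), and 0 members passed over all genes or adjusted over the list alone. The medians of the NMD machinery in replicate 3 against replicate 1 were -1.36 in pad4 and -1.22 in the double mutant, larger than its difference between genotypes.

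In the defence lists set beforehand few genes could be read, and none but the defensins passed. Of ethylene and jasmonate defence these were 2 of 6 listed genes, and of salicylic acid defence 3 of 29. The 2 measured genes of ethylene and jasmonate defence were PDF1.2 and PDF1.2b, both past the threshold over all genes and adjusted over the list alone. Salicylic acid defence had 3 measured genes, a median log2 fold change of 0.13 and a camera adjusted p of 1.00; SAG101, a partner of EDS1, had 0.18 and the transcription factor WRKY53 0.13. Among genes of pattern-triggered immunity, the kinase BIK1 had 0.06 and WRKY22 -0.18, and WRKY6, on the senescence list, had 0.24. BCAT4, an enzyme of aliphatic glucosinolate synthesis, went from 1682 ± 149 to 1086 ± 94.7 signal units (SD, n = 3), a log2 fold change of -0.63 that did not pass, and UGT74C1 of the same pathway had 0.13.

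Lists of photosynthesis, the organelles and stress were not called in that fit either. Only 4 of 30 listed nuclear photosynthesis genes and 3 of 15 cold and drought genes could be read. The 4 nuclear photosynthesis genes had a median of 0.02 and a camera adjusted p of 1.00, with 0.15 for RCA, the rubisco activase, and -0.07 for LHCB4.2. Of 66 chloroplast-encoded genes 42 had a lower and 24 a higher value (median -0.06, camera adjusted p = 0.22), with 0.50 for ycf3 and -0.37 for atpH. The chloroplast list was called in opposite directions by different fits at camera's preset correlation: higher with stage as a covariate (median 0.19, adjusted p = 9.6e-04), lower without pad4 replicate 1 (median -0.22, adjusted p = 1.7e-04) and lower without double mutant replicate 3; with an estimated correlation the adjusted p was 0.93. Among 9 mitochondrion-encoded genes the median was 0.30 (camera adjusted p = 0.46; 0.56 as the median with a filter at 50%, where the list was called with camera adjusted p = 0.0030; adjusted p = 0.78 with an estimated correlation), with 0.85 for nad4 and 0.74 for ccb382. The cold and drought genes COR47, COR15B and COR15A all had positive values (median 0.65, camera adjusted p = 0.17), with 0.91 for COR15A, 0.65 for COR15B and 0.58 for COR47. The median of this list ran from 0.29 to 1.63 over 20 alternatives, 6 of which called it, among them the fits with stage as a covariate (1.63), without pad4 replicate 3 (1.29) and without both replicate 3 arrays, all at the preset correlation (adjusted p = 0.38 with an estimated correlation and 0.52 by fry in the fit without covariates). COR15B was at 1474 ± 1233 signal units in pad4 (SD, n = 3), so its spread between pad4 arrays was close to its mean, and the median of the 3 genes in replicate 3 against replicate 1 was 2.26 in pad4 and 1.12 in the double mutant. GI, a clock gene, had 0.62, UGT78D2 of the flavonoid pathway -0.26 and FMA, a guard cell regulator also written FAMA, -0.13. The reference genes had a median of 0.09 (camera adjusted p = 1.00), with 0.12 for SAND and 0.09 for TIP41; their sign turned under several alternatives. In each of these lists 0 members passed over all genes or adjusted over the list alone.

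The largest difference among the arrays did not follow genotype. The first principal component held 64.9% of the variance and placed both replicate 1 arrays at one end (44.2 for pad4, 43.0 for the double mutant) and both replicate 3 arrays at the other (-67.2 and -37.8). The second, with 15.4%, put all pad4 arrays above 0 and all double mutant arrays below it. The mean log2 3'/5' ratio of the actin and GAPDH controls, a measure of RNA integrity, ran from 1.209 in pad4 replicate 1 to 1.997 in pad4 replicate 3. Its size depends on the control probe sets chosen. Another GAPDH pair on the array averaged 1018 units (3') and 1020 (5') in pad4, and 1117 and 1152 in the double mutant (n = 3).

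**Figure D3:**
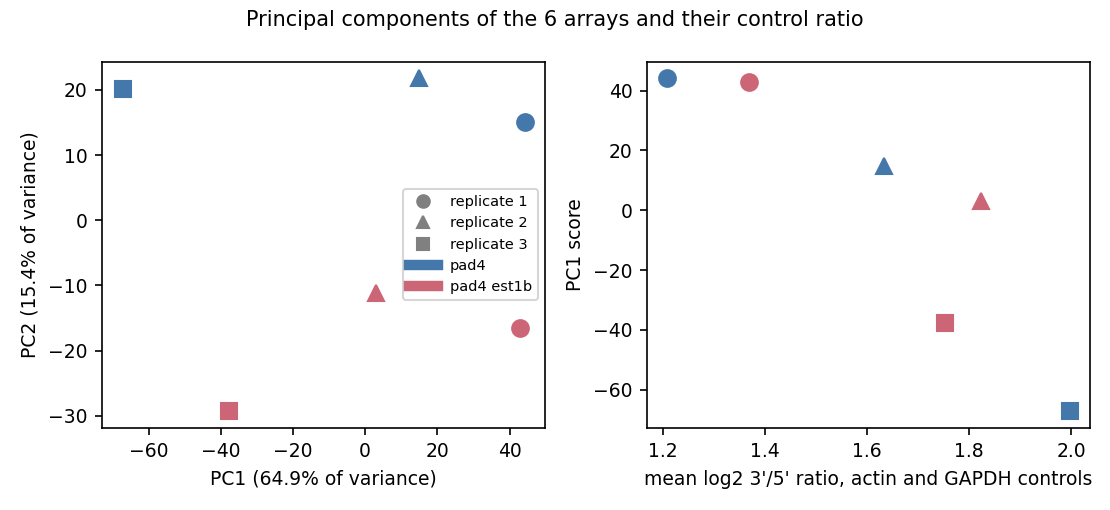
Left, scores of the 6 arrays on the first and second principal components of log2(signal + 10); right, first component score against the mean log2 3'/5' ratio of the actin and GAPDH controls, with colour for genotype and marker shape for replicate number. The pad4 replicate 3 array has the lowest score (-67.2) and the highest ratio (1.997).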

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

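The test in this part was chosen only after the control values had been seen. The array's 25S ribosomal RNA control, a probe set that the comparisons leave out, stood out because its mean in the double mutant lay above the highest pad4 array. It averaged 706 ± 660 signal units in the double mutant and 233 ± 205 in pad4 (SD, n = 3). The arrays of replicates 1, 2 and 3 had 21.3, 430 and 248 units in pad4 and 35.9, 1356 and 728 in the double mutant. An exact two-sided permutation test over the 3 and 3 arrays gave p = 0.3, and the smallest p this design allows is 0.1. No explanation was tested for this signal.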

How the results depend on the processing

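The fits with the control 3'/5' ratio as a covariate and without both replicate 3 arrays were chosen only after the arrays had been seen. The limits are 3 arrays per group, 12804 probe sets bright enough to use and 6892 of these with a gene to name, and the cause of the changes listed here was not tested. The reported NMD targets kept their direction and their call in 20 of 20 alternatives, with medians from 0.36 to 1.09 and adjusted p up to 1.38e-04 by limma's camera; with an estimated correlation and with fry 0 fixed and 0 added lists were called. The planned test of transcript features that trigger NMD was not run, since no annotation of untranslated regions was at hand.

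Against 5 probe sets called by limma, 0 were called without the offset (smallest adjusted p 0.060, 581 unadjusted), without the filter (0.11, 1156), without probe sets open to cross-hybridisation (0.060, 543), with stage as a covariate (0.27, 196) and among the samples labelled 5.10 (0.12, 351). Quantile normalization gave 2, median centring 1, the control ratio as a covariate 36 and the fit without both replicate 3 arrays 19. An offset of 30% gave 5, of which 4 were shared with the main fit and CPUORF47 was not (adjusted p = 0.070 by limma). A filter at 50% gave 6, and trend and robust options 6. Array weights gave 2274 (1140 higher, 1134 lower), with weights that had not converged (26.5 for pad4 replicate 2, 0.164 for pad4 replicate 3). With single arrays left out the calls ran from 0 to 9, the fixed lists called from 1 to 3 and the added lists from 2 to 4. Of the probe sets at an unadjusted p under 0.05, 74.0% were higher in the double mutant, 66.9% after quantile normalization, 63.3% after median centring and 48.4% with array weights.

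With the replicate number as a block (replicate block), limma called 81 probe sets, 70 higher and 11 lower, with all 5 among them, and 2 fixed lists; AT2G05540 (adjusted p = 0.0060), AT3G53980 (0.020) and AT5G48490 (0.034) were among the lower ones. The deviations of same-numbered arrays from their group means correlated at 0.83, 0.0 and 0.68 for replicates 1, 2 and 3. By these deviations pad4 replicate 2 correlated best with double mutant replicate 1 (0.39), so the numbers were not taken as pairs. In log2 signal, however, each pad4 array was closest, among the double mutant arrays, to that of its own number (Pearson 0.969, 0.951 and 0.948). Replicate 2 minus replicate 1 also correlated between the genotypes (0.52). Replicate 3 minus replicate 1 did so too (0.81). Both replicate 2 arrays lie between the other arrays of their genotype on the first component (14.8 and 3.1), so their deviations tell little about pairing. Arrays of the same number thus shared differences, and the main fit leaves these in the residual spread.

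Fixed lists called, against 1, were 2 with a filter at 50%, 2 with array weights, 2 without both replicate 3 arrays, 3 with stage as a covariate and 3 among the samples labelled 5.10. Added lists called, against 2, were 0 without the filter, 0 with array weights, 1 with stage as a covariate, 3 with the control ratio as a covariate and 4 among the samples labelled 5.10. For lists the direction is that of camera, which follows all members: 522 of 591 comparisons kept it and their side of the threshold, 15 were weaker, 19 stronger and in 35 both it and the sign of the median turned. In 38 further comparisons, over 13 lists, the median alone changed sign, to values between -0.10 and 0.12, with 1 of them called. For named genes 653 of 775 kept direction and side, 44 were weaker, 35 stronger and 43 turned. No result that turned had passed the threshold before.

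Values of the lists whose direction by camera turned together with the median, and of the genes that turned, are given here. With stage as a covariate, and with the same values among the samples labelled 5.10 (1 pad4 array against 3), they were 0.17 for autophagy, 0.53 for calmodulin-like genes, -0.048 for chaperones and heat, 0.19 for chloroplast-encoded genes, -0.17 for the NMD machinery and its member UPF3, 0.058 for the added list of nuclear photosynthesis, -0.12 for the reference genes and their member TIP41, 0.021 for SWEET transporters, -0.0954 for UGT74C1, -0.11 for GI, -0.14 for BIK1, -0.054 for RCA, 0.086 for LHCB4.2, -0.31 for SAND and -0.15 for SAG101. Cell division had -0.0161 in both fits, where the direction by camera turned only among the samples labelled 5.10. With array weights the values were 0.20 for calmodulin-like genes, -0.13 for chaperones and heat, -0.083 for CYP71B, -0.34 for UGT74C1, 0.33 for WRKY22, 0.10 for LHCB4.2, -0.39 for TIP41 and -0.089 for SAG101. Without both replicate 3 arrays they were 0.35 for calmodulin-like genes, -0.081 for cell division, -0.053 for the reference genes and their member SAND, -0.29 for UGT74C1, 0.26 for WRKY22, -0.0242 for BIK1, 0.025 for LHCB4.2 and -0.19 for TIP41. A filter at 50% gave 0.346 for calmodulin-like genes, median centring -0.0111 for BIK1, and quantile normalization -0.0022 for the reference genes and TIP41 and -0.031 for BIK1.

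With single arrays left out the lowest and highest values were -0.38 and 0.33 for calmodulin-like genes, -0.047 and 0.30 for chaperones and heat, -0.22 and 0.095 for chloroplast-encoded genes, -0.18 and 0.053 for iron, -0.12 and 0.045 for the added list of nuclear photosynthesis, -0.18 and 0.20 for the reference genes, -0.039 and 0.27 for salicylic acid defence and its member WRKY53, -0.36 and 0.011 for SWEET transporters, and -0.029 and 0.12 for UDP-glycosyltransferases. For single genes they were -0.25 and 0.39 for UGT74C1, -0.54 and 0.21 for FMA, -0.46 and 0.17 for WRKY22, -0.17 and 0.20 for BIK1, -0.0012 and 0.25 for RCA, -0.25 and 0.073 for LHCB4.2, -0.18 and 0.34 for SAND, -0.27 and 0.34 for TIP41, and -0.15 and 0.37 for SAG101.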

Other observations

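In this part the tests on splits of the arrays, on differences between replicates 1 and 3 and on the 3 patterns weighed were chosen only after the results had been seen, while the 19 added lists were written before any fold change was computed. Genes of the cell wall and of auxin response, named here after their values were seen, were called lower as groups in the double mutant at camera's preset correlation, and not with an estimated correlation. Of 14 expansins and xyloglucan-modifying enzymes, 11 had a negative value (median log2 fold change -0.34, adjusted p = 2.74e-04 by limma's camera; adjusted p = 0.62 with an estimated correlation), with -1.16 for XTH19, -0.82 for XTH32, -0.65 for EXPB1 and 0.54 for XTH18. All 6 auxin genes had negative values (median -0.39, adjusted p = 0.0030 by limma's camera; adjusted p = 0.59 with an estimated correlation), with -1.05 for the glucosyltransferase gene IAGLU, -0.64 for IAA29 and -0.44 for HAT2. In both lists 0 members passed over all genes or adjusted over the list alone. The call on the cell wall list was lost without the filter, with stage as a covariate, among the samples labelled 5.10, with array weights, without pad4 replicate 3 and without both replicate 3 arrays; that on the auxin list was lost without the filter, with stage as a covariate and with array weights. Over the alternatives the median ran from -0.44 to -0.050 for the cell wall list and from -0.57 to -0.19 for the auxin list, which had -0.52 with stage as a covariate. Other splits of the 6 arrays called the cell wall list in 4 cases, with an absolute median of up to 0.36 against 0.34 for the genotypes, and the auxin list in 0 cases, with up to 0.39 against 0.39. The other 16 lists tested had medians from -0.31 to 0.37 and adjusted p from 0.11 to 0.72 by limma's camera, and 1 list, of the endoplasmic reticulum body, kept too few genes to test. At the preset correlation 5 of the 16 were called in some alternative: cold and dehydration in 4 (higher, median up to 0.92; adjusted p = 0.77 with an estimated correlation over all arrays), calmodulin-like genes in 2 with opposite directions (0.53 among the samples labelled 5.10, -0.38 without pad4 replicate 1; adjusted p = 0.76 with an estimated correlation over all arrays), autophagy in 2, and tau glutathione transferases and defence in 1 each. With an estimated correlation over all arrays the camera adjusted p was 0.76 for autophagy, 0.72 for tau glutathione transferases and 0.76 for defence. Among the 18 genes of the added defence list (median 0.06), the defensin gene PDF1.4 had -0.96 and the thionin gene THI2.2 -0.97, neither passing.

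Some cold-responsive and chloroplast transcripts had more signal in replicate 3 than in replicate 1 of both genotypes, compared without a test since each is 1 array. The median log2 difference was 2.26 in pad4 and 1.12 in the double mutant for the 3 cold and drought genes, and 0.48 and 0.44 for the 66 chloroplast-encoded genes. The genes named next are among the largest differences. COR27, a cold and clock gene, had 23.1, 16.7 and 547 signal units in pad4 replicates 1 to 3 and 124, 156 and 529 in the double mutant, and psbA of photosystem II had a log2 difference of 2.93 in pad4 and 1.74 in the double mutant. EIN3, the transcription factor of ethylene response, had -2.64 and -2.12, the ubiquitin protease gene UBP15 -2.11 and -2.26, and the lipase gene SDP1 -2.32 and -2.47. At least 4-fold in both genotypes, 21 probe sets were higher and 101 lower in replicate 3. Without both replicate 3 arrays limma called COR27 higher in the double mutant (log2 fold change 2.33, adjusted p = 0.022; 1.53 and 1.00 with all arrays), as it did AT4G29780 (2.66, adjusted p = 0.013; 1.55 and 1.00 with all arrays) and AT5G52050 (2.17, adjusted p = 0.023; 1.35 and 0.96 with all arrays). With the control ratio as a covariate, limma called 3 reported NMD targets: AT3G53400 (adjusted p = 0.0019), AT5G45430 (adjusted p = 0.0053) and AT1G36730 (adjusted p = 0.0062).

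Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The genotype split gave 5 called probe sets by limma and the highest other split 0, so 1 of 10 splits reached the count. For lists set beforehand the genotype split gave 1 and the highest other 3, with 9 of 10 splits at 1 or more; for added lists it gave 2 and the highest other 6, with 8 of 10 at 2 or more. At an unadjusted p under 0.05 the split of pad4 replicates 1 and 2 with double mutant replicate 1 gave 4128 probe sets and the genotype split 569.

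For the higher values of the reported NMD targets in the double mutant (median 0.76), unequal RNA quality was weighed only as far as the control ratio measures it. It is argued against by close mean log2 ratios, 1.61 ± 0.39 in pad4 and 1.65 ± 0.24 in the double mutant (SD, n = 3). With the trend of the list on the ratio within genotypes, this difference gives a shift of -0.0435 (95% interval -0.10 to 0.017). Means this close allowed only a small shift and the interval holds the error of the slope alone, so the shift is no further evidence. A rise common to genes of the same signal is argued against by random lists matched on signal, whose central 95% of medians ended at 0.2529 and whose highest median was 0.65. These lists lack the correlation among the list's members (estimated at 0.25), so they do not measure how far the list moved beyond chance. The earlier stage label of 2 pad4 samples stays open: the median among the samples labelled 5.10 was 0.362, under 0.5 of the main value with the list still past the threshold (adjusted p = 1.17e-04 by limma's camera at the preset correlation), and rests on a single pad4 array, replicate 1, which lies at an end of the main axis. The list was also called in 3 other splits of the arrays, where its largest absolute median was 0.66. The hypothesis that loss of EST1B slows the decay of these transcripts was not tested beyond the list, and the estimated correlation (adjusted p = 0.18) leaves open whether the list moved beyond chance.

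For the main axis of variation between the arrays, the stage labels as its only cause are argued against by the double mutant. There the label is the same, yet replicate 3 minus replicate 1 followed that in pad4 at r = 0.8066 (n = 12804 probe sets of single arrays, Spearman 0.82). These arrays lie toward the ends of the axis, which favours a high r. The difference was larger in pad4, where the label also differs (SD over probe sets 0.97 against 0.77), so a part from stage stays open. Genotype is argued against by an overlap of 72.53% between the ranges of the 2 genotypes on the axis. Unequal RNA quality stays open: the axis followed the mean log2 control ratio at r = -0.8897 (n = 6, exact permutation p = 0.022, adjusted over 3 measures 0.033). Taken singly, the GAPDH ratio gave r = -0.91 (exact permutation p = 0.0097) and the actin ratio r = -0.71 (exact permutation p = 0.12). Without pad4 replicate 1 and double mutant replicate 1, both at the same end of the axis, r for the mean ratio was -0.79 (n = 4, exact permutation p = 0.21). The array at the other end, pad4 replicate 3, was kept there, and 4 arrays are too few to decide. Controls other than the ratio also set both replicate 1 arrays apart. The cre control had 4600 units in pad4 replicate 1 and 4513 in double mutant replicate 1. In replicates 2 and 3 it had 5937 and 6492 in pad4, and 6848 and 6197 in the double mutant. The 25S ribosomal RNA control was also lowest in replicate 1 of each genotype (21.3 and 35.9). Technical causes other than RNA quality were not tested and stay open. No biological explanation of the axis was tested.

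The rise of the 2 defensin probe sets in the double mutant was set against 2 explanations. Unequal RNA quality, as far as the control ratio measures it, is argued against by the close mean log2 ratios (1.61 in pad4, 1.65 in the double mutant). With the trends on the ratio within genotypes, this difference gives shifts of 0.0458 for PDF1.2 (95% interval -0.011 to 0.10) and 0.010 for PDF1.2b (95% interval -0.060 to 0.080). Means this close allowed only small shifts, and the intervals hold the error of the slopes alone. Cross-hybridisation stays open: the log2 difference between the 2 probe sets ranged over 0.1378 in the double mutant samples and over 1.24 in all 6 arrays, and 2 genes that rise together would also give the small range. Which defensin gene rose stays open, and so does the hypothesis that the rise follows from loss of EST1B, for which the genotype labels are the only measure.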
